A study of Homo sapiens with 12 samples.

How the data were processed

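Polyadenylated RNA of a pair of human gastrointestinal stromal tumour sublines was sequenced in 12 libraries on a BGISEQ instrument with single reads of 50 bases, per the labels. The submitters' processing notes name fastp 0.22.0, HISAT2 2.2.0 and featureCounts 2.0.6, with no role or order, and list the genome builds hg38, GRCm38 and mm10 without saying which build served these human samples. The deposited table holds 1 column per library and 18058 gene symbols. Its values are expected counts as deposited by the authors: they are not normalised, they contain fractions, and 24% of them are whole numbers within a tolerance of 1e-9. How fractional counts arose from the named tools is not stated. T1R libraries carry column names that begin with T882 in the table, and each column was assigned through the column name given in that sample's description. No sample was left out.

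Counts were rounded to whole numbers. In the table, 0 entries lacked a gene name and 37 genes had no read in any library. Genomic positions came from GENCODE release 29 (GRCh38), to which 17800 of the 18058 symbols were matched by name or by current symbol. The kit or alignment strand setting is not given, so genes that overlap another coding gene and families of near-identical copies have uncertain counts; the text says so where it names one.

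Differential expression was tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM scaling. The filter filterByExpr (minimum count 10, minimum total count 15) left 14085 genes. A quasi-likelihood fit with robust dispersion estimation used all 12 libraries and 6 group means, leaving 6 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of its F statistic. For a large fold with few reads in one group, this SE can be smaller than the counting error. The p-values measure the spread between the 2 libraries of a group. That spread was low: the common biological coefficient of variation was 0.0252, although the labels call the libraries biological replicates, so small changes passed the test. Whether replicates were separate cultures is not stated. For each pair of replicates, the chi-square per degree of freedom over genes with at least 20 reads was between 1.80 and 2.60, above the value of 1 that sampling alone would give. CPM were computed on the TMM-scaled library sizes and are given as mean ± SD with n = 2 libraries per group.

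Each hairpin was compared with the control of its own line, the mean of both hairpins with that control, the lines with each other in that effect (an interaction contrast), sh2 with sh1, and the T1R control with the 882R control. A change with both hairpins means a call in the same direction with each. Because both hairpins share 2 control libraries, 20 data sets with unchanged hairpin groups were simulated against the same controls. Overlap between lines, which share no library, was tested with one-sided Fisher's exact tests. Correlations are across genes, which are not independent replicates.

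The comparisons, the gene lists and the rule for named genes were fixed before the data were examined. That rule took IL6 in every comparison. In each line it took the 10 genes with the largest rise and the 10 with the largest fall among those called with both hairpins, beyond both controls in every knockdown library, and at a mean of at least 5 CPM. It also took up to 4 called members of each list by adjusted p, up to 10 genes per direction shared by the lines, and the leading genes of the interaction, hairpin and control comparisons. Genes chosen after their values were seen are named as such.

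The gene lists were the IL6 receptor complex and JAK/STAT3 response, inflammatory cytokines and NF-kB response, angiogenic factors and receptors, GIST lineage genes, MAPK output genes, bypass receptors with ligands and drug efflux, BCL2 family and caspases, proliferation, p53 targets, interferon response, ATF4 and unfolded protein response, hypoxia and glycolysis, cholesterol synthesis and uptake, autophagy and lysosome, mesenchymal and matrix genes, interleukin and chemokine receptors, ribosomal protein genes, replication-dependent histones, and markers of epithelial, endothelial, blood, and fibroblast or smooth muscle cells. A list needed 3 tested members, and the list of mitochondrial messenger genes is not analysed here. The other 22 lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The fry test asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Adjusted p-values of lists were corrected over the 22 lists of a comparison.

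The fit was tested on simulated data drawn from the same depths, with 200 genes changed in each comparison, 50 of them at each size. In the real data 83.8% (882R) and 80.2% (T1R) of tested genes were called for the mean of both hairpins. The simulation therefore does not test the scaling where most genes change. For the mean of both hairpins in 882R it recovered 35 of 50 genes changed 1.25-fold, 41 of 50 changed 2-fold and 48 of 50 changed 4-fold, with 9 unchanged genes called; in T1R these were 38, 43, 46 and 15. Folds against a group with no read in any library are lower bounds computed against 3 reads per library, and ratios with 1 to 3 reads carry an exact 95% interval. Both cover counting error only, because reads without molecular identifiers are not independent molecules.

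Alternatives were size factors of the DESeq2 type (RLE), DESeq2 1.42.0 itself, no filter, a stricter filter of 1 CPM in every library of a group, a fit of each line alone, replicate number as a block, a minimum log2 fold change of 1, each library left out in turn (12 fits), and removal of a trend with gene span, which was added after seeing the data. In the leave-one-out fits, a group left with 1 library was assumed to vary like the others. RLE scaling shifted the median knockdown effect by 0.0027 (882R) and 0.0046 (T1R) on the log2 scale, and library totals shifted it by 0.0051 and -0.0261. All of these scalings are relative to the reads of a library, so their closeness cannot show whether the total RNA of the cells changed. The balance of higher and lower genes and the sign of small list medians depend on this relative zero. The labels give no batch, date or lane. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Results of some single genes are not reported here.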

Results

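Messenger RNA was measured in 12 libraries from a pair of resistant human gastrointestinal stromal tumour (GIST) sublines. GIST is a sarcoma of the gut wall related to the pacemaker cells of the intestine. The sublines, 882R and T1R, were derived from the drug-sensitive lines GIST-882 and GIST-T1, and the labels do not name the drug. Each subline was sequenced as a control, described as a blank control with the library name NC, and after transfer of either of 2 short hairpin RNAs against interleukin 6, called sh1 and sh2. This gives 6 groups of 2 libraries, which the labels call biological replicates. What the control cells carry is not stated. Any difference between knockdown and control libraries may therefore come from lowered IL6, from the hairpin vectors or from a batch. These cannot be told apart here, even where both hairpins moved alike. The term knockdown effect is used below for the difference only. In 882R, the libraries held 20784454 and 20770912 assigned reads for the control, 21532306 and 19701509 for sh1, and 21290192 and 21309417 for sh2. In T1R, they held 17144641 and 21173864 for the control, 21634776 and 21554605 for sh1, and 21632649 and 21578721 for sh2. Across genes, replicates of a group correlated at r = 0.992 to 0.993 in log2 CPM, and control and knockdown libraries of a line at r = 0.885 to 0.919. The first principal component held 78.9% of the variance and separated all 4 control libraries (91.36 to 92.92) from all 8 knockdown libraries (-61.76 to -34.21).

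The first comparison asked how far each hairpin lowered its target. IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002, plus strand, GRCh38) encodes interleukin 6, an inflammatory cytokine that signals through JAK and STAT3. Its messenger RNA fell with both hairpins in both lines. In 882R it stood at 221.4 ± 2.05 CPM (SD, n = 2) in the control, 26.4 ± 1.83 CPM with sh1 and 8.22 ± 0.664 CPM with sh2, which is 11.9% and 3.71% of the control. In T1R the control had 111 ± 5.22 CPM, sh1 17.4 ± 1.64 CPM (15.7% of the control) and sh2 9.69 ± 1.64 CPM (8.73%). The log2 fold changes were -3.07 for sh1 (adjusted p = 1.11e-31) and -4.75 for sh2 (adjusted p = 6.55e-35) in 882R, and -2.67 (adjusted p = 4.83e-28) and -3.52 (adjusted p = 3.58e-30) in T1R, with both knockdown libraries below both controls each time. IL6 was lower with sh2 than with sh1 in 882R (log2 difference -1.68) and in T1R (log2 difference -0.84). The T1R control held less IL6 than the 882R control (log2 fold change -0.998, adjusted p = 1.99e-18).

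**Figure D1:**
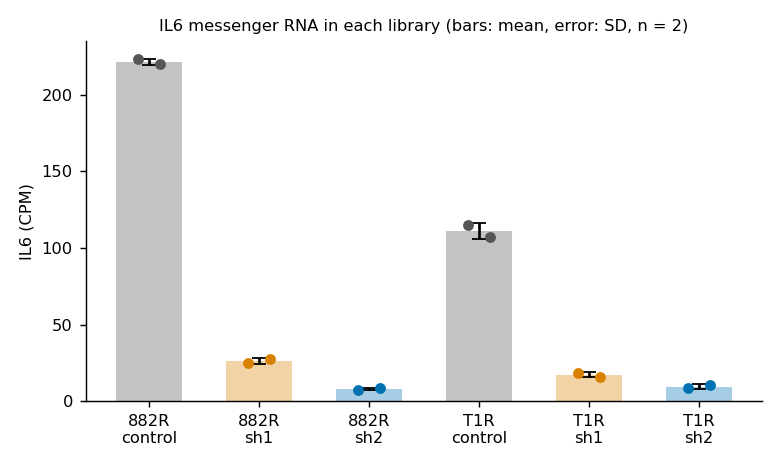
IL6 messenger RNA in CPM for each of the 12 libraries (points), with the mean (bars) and SD (error bars, n = 2) of each group. All 4 control libraries stand at 107.4 CPM or more, and all 8 knockdown libraries at 27.7 CPM or less.

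The next comparisons asked what else differed in 882R when IL6 was lowered. The lists of interferon response, inflammatory cytokine and matrix genes had medians below 0 in 882R (-3.66, -1.99 and -1.64), and transcripts of the metallothionein MT1M, the cyclins CCNE1 and CCNE2 and the cell death gene BCL2L11 rose. The chemokine CXCL10, which attracts T cells, fell from 64.5 ± 4.64 CPM to 0.247 CPM with sh1 and 0.0928 CPM with sh2 (log2 fold change -8.68 ± 0.14, SE). CCL2, a monocyte attractant, fell from 374.9 CPM to 5.88 and 2.78 CPM (log2 fold change -6.54 ± 0.05). TDO2, an enzyme of tryptophan breakdown, fell by 7.12 on the log2 scale from 10.7 CPM, and CCL8, another monocyte attractant, was at least 133-fold lower (19 CPM in the control and no read in the knockdown libraries). Among genes that rose, the metallothionein gene MT1M went from 0.0964 CPM to 15.35 and 32.96 CPM (log2 fold change 7.78 ± 0.21), although near-identical family members make its count uncertain. The lipid carrier gene APOE rose from 0.121 CPM to 16.35 and 16.08 CPM (log2 fold change 6.999 ± 0.22), and DDN, known from neurons and kidney podocytes, rose by 5.35 ± 0.21 on the log2 scale.

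The interferon response list moved as a block in 882R: all 37 tested members fell, with a median log2 fold change of -3.66 (camera adjusted p = 2.44e-110). IFIT1, which binds viral RNA, fell from 1344 CPM to 38.9 and 18.6 CPM (log2 fold change -5.65 ± 0.04), and the antiviral GTPase gene MX1 (-4.66) fell with it. Of 30 inflammatory cytokine and NF-kB genes, 27 fell, 1 rose and 2 did not pass (median -1.99, adjusted p = 1.97e-20), among them CSF1, a macrophage growth factor (2464 CPM to 338.1 and 172.6 CPM), SOD2 (log2 fold change -2.52), which detoxifies superoxide, and the neutrophil attractant CXCL1 (-3.41). In the IL6 receptor and JAK/STAT3 list, 27 of 37 fell and 10 rose (median -1.26, adjusted p = 5.77e-10). STAT3, the transcription factor downstream of the IL6 receptor, fell by 1.86 on the log2 scale, as did the survival gene BCL2L1 (-1.92) and the oxygen-sensing factor HIF1A (-1.94). SOCS3, a feedback inhibitor induced by STAT3 and chosen here after its values were seen, fell by 2.11.

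Angiogenesis is named in the title of the series. Of 49 angiogenic factors and receptors in 882R, 34 fell, 11 rose and 4 did not pass (median -1.07, adjusted p = 1.42e-05). The matricellular gene CCN1 fell from 804 CPM to 134.6 and 116.5 CPM (log2 fold change -2.68 ± 0.03), and the growth factor gene FGF2 (-1.95) and the collagen-degrading protease gene MMP2 (-1.55) fell too, while HBEGF, a ligand of the EGF receptor, rose from 25.04 CPM to 140.8 and 143.1 CPM. Chosen after their values were seen, the vascular growth factor gene VEGFA fell by 1.47 ± 0.03 (530.3 CPM to 203 and 180.9 CPM), and its relative VEGFC (-2.48) and the vessel-stabilising ligand gene ANGPT1 (-2.80) fell as well. Mesenchymal and matrix genes fell in 31 of 39 cases and rose in 5 (median -1.64, adjusted p = 4.09e-24): COL6A3, a collagen VI chain, went from 2041 CPM to 220 and 125.7 CPM, and COL1A2, a collagen I chain (-3.96), and the microfibril gene FBN1 (-3.93) fell too. The hypoxia and glycolysis list had 21 members that fell and 11 that rose of 35 (median -0.25, adjusted p = 2.71e-05), including CA9, a carbonic anhydrase induced by low oxygen (94.1 CPM to 1.79 and 0.88 CPM), the glucose transporter gene SLC2A1 (log2 fold change -3.24) and HK2, which phosphorylates glucose (-2.93). Once the trend with gene span described further on was removed, 24 members fell and 7 rose (median -0.605, adjusted p = 3.62e-09). The medians of the angiogenic and matrix lists then shrank to -0.791 (adjusted p = 1.87e-08) and -1.178 (adjusted p = 1.48e-23).

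Lists tied to GIST and drug response moved less evenly in 882R. Among 18 GIST lineage genes, 6 rose, 8 fell and 4 did not pass, with a median of 0.06, a mean of -0.13 and no call (adjusted p = 0.778). PLAT, the tissue plasminogen activator gene, fell by 2.38 and BARX1, a stomach patterning factor, rose by 0.95. Of 26 MAPK output genes, 18 fell and 7 rose (median -0.58, adjusted p = 0.0282, but adjusted p = 0.14 with an estimated correlation), led by the immediate early genes EGR1 (-3.16) and FOS (-2.19). Bypass receptors, ligands and drug efflux genes fell in 22 of 28 cases and rose in 2 (median -1.29, adjusted p = 4.06e-07): examples are the efflux pump gene ABCC1 (-2.66) and the receptor genes EGFR (-2.87) and MET (-2.57). The members of this list span a median of 86.7 kb on the genome, and its median shrank to -0.80 once the span trend was removed (adjusted p = 6.84e-04). In the BCL2 family and caspase list 16 of 30 fell and 10 rose (median -0.15, adjusted p = 0.52); BCL2L11, which encodes the death-promoting protein BIM, rose from 5.99 CPM to 48.3 and 48.6 CPM, and the caspase inhibitor gene BIRC3 fell by 3.61. The GIST lineage and BCL2 family medians were 0.14 and -0.28 without the span trend, again with no call.

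Cell cycle, stress and housekeeping lists in 882R also held both directions. Of 40 proliferation genes, 22 rose and 16 fell (median 0.24, adjusted p = 7.23e-05); the cell cycle factor E2F1 rose from 50.6 CPM to 300.8 and 366.7 CPM, and the cyclin genes CCNE1 and CCNE2 rose by 3.64 and 3.20. Without the span trend, 19 rose and 19 fell (median 0.02, adjusted p = 0.0203). The p53 targets split into 13 that rose and 13 that fell of 28, with a median of 0.10, a mean of -0.10 and no call (adjusted p = 0.568). Of the p53 targets, 8 rose and 14 fell without the span trend (median -0.17, adjusted p = 0.0119). PLK2, a kinase gene, fell by 1.44. Of 31 genes of the ATF4 and unfolded protein response, 19 fell and 12 rose (median -0.75, adjusted p = 0.00444), including the stress gene DDIT4 (-2.73) and the protein disulfide isomerase gene PDIA4 (-1.63). The median of this list was -0.505 without the span trend (adjusted p = 2.02e-09). Cholesterol genes fell in 13 and rose in 9 of 23 cases without a call (median -0.22, adjusted p = 0.339). They were called without the span trend (median -0.315, adjusted p = 0.00441). Autophagy and lysosome genes rose in 25 and fell in 11 of 39 cases (median 0.31, adjusted p = 0.0457, but adjusted p = 0.0816 with an estimated correlation), for example VPS18 (1.75), which acts in vesicle fusion, against ATG7 (-2.49). The call ended without the span trend (median -0.03, adjusted p = 0.126). Interleukin and chemokine receptor genes fell in 16 and rose in 7 of 26 cases without a call (median -0.46, adjusted p = 0.197). Of 44 ribosomal protein genes, 38 rose and 2 fell (median 0.41, adjusted p = 2.57e-04, but adjusted p = 0.276 with an estimated correlation). Once the span trend was removed, 8 rose and 29 fell, without a call (median -0.18, adjusted p = 0.298). RPL15 rose by 0.74 and RPL3 fell by 0.64. Replication-dependent histones rose in 5 and fell in 4 of 11 cases, with a median of -0.01, a mean of 0.66 and no call (adjusted p = 0.568). Of these, 3 rose and 6 fell without the span trend (median -0.736, adjusted p = 0.761).

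Markers of other cell types changed in 882R as well. Epithelial markers fell in 8 and rose in 2 of 11 cases (median -1.13, adjusted p = 0.0723; median -1.32 and adjusted p = 0.00174 without the span trend), and 7 of the 11 stood at 1 CPM or more in the control; the keratin gene KRT18 fell by 1.13. Endothelial markers fell in 6 and rose in 4 of 10 cases (median -1.28, adjusted p = 0.52; median -0.73 and adjusted p = 0.646 without the span trend), with the transcription factor ERG at -2.61 and the junction gene ESAM up by 3.62 from 0.507 CPM. Blood cell markers rose in 6 of 8 cases and fell in 0 (median 2.53, adjusted p = 0.242), and 1 of the 8 reached 1 CPM in the control. CD14, a monocyte receptor gene, rose from 0.87 CPM to 6.93 and 9.40 CPM, and CD68, a lysosomal gene of macrophages that many cells express, rose by 0.54 from 96.1 CPM (-0.07 without the span trend). Fibroblast and smooth muscle markers fell in 9 and rose in 2 of 15 cases (median -1.02, adjusted p = 7.23e-05); 8 of the 15 belong to other lists too, such as COL1A1 (-2.52), and DCN, a matrix proteoglycan gene, fell by 1.88.

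By number, 11287 of 14085 tested genes differed between sh1 and the control in 882R (5621 higher, 5666 lower, 4719 at least 2-fold). With sh2, 11652 differed (5838 higher, 5814 lower, 5221 at least 2-fold). For the mean of both hairpins, 11810 genes differed (5884 higher, 5926 lower), or 83.8%. With both hairpins in the same direction, 5054 genes were higher and 5169 lower, against 2330 and 2339 for independent calls, and 164 were called in opposite directions. Their fold changes correlated at r = 0.943 across genes, against a mean of 0.504 in simulations of unchanged groups, in which at most 3 genes were called with both. The controls were not split between the hairpins, which would leave 1 control library for each. Counts adjusted over the list alone equalled those over all genes in every list of 882R except the matrix list, where 32 rather than 31 fell. The camera calls numbered 13 of 22 lists, 10 with an estimated correlation and 22 with fry; the 3 calls lost with an estimated correlation were those given beside MAPK output, autophagy and ribosomal protein genes.

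The same comparison in T1R asked whether the second line responded likewise. In T1R, the interferon response, inflammatory cytokine and matrix lists again had medians below 0 (-3.07, -1.49 and -1.30), and transcripts of MT1M and the protease MMP3 rose. TNFSF10, the gene of the death ligand TRAIL, fell by 7.02 ± 0.29 on the log2 scale from 8.49 CPM, and TDO2 (-7.40 ± 0.17 from 28.35 CPM), CXCL10 (-6.28 ± 0.14 from 29.93 CPM) and CCL2 (-5.77 ± 0.05 from 328.7 CPM) fell alongside. CCL8 had 438 reads in the 2 controls and 1 read in the 4 knockdown libraries, a ratio of 970 (95% interval 173 to 38400). MT1M rose from 0.198 CPM to 41.47 and 43.21 CPM (log2 fold change 7.64 ± 0.16, with the same uncertainty about family members), the matrix protease gene MMP3 from 2.201 CPM to 73.0 and 107.9 CPM (5.34 ± 0.09), APOE by 5.15 ± 0.21 and LCP1, an actin-bundling gene of blood cells and many tumours, by 4.98 ± 0.07. The cytokine gene IL17F had 1 read in the controls and 441 in the knockdown libraries, a ratio of 199 (95% interval 35.5 to 7880).

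In T1R, too, all 37 interferon response genes fell (median -3.07, adjusted p = 6.67e-115), IFIT1 from 1149 CPM to 50.7 and 31.2 CPM, with IFIT2 at -4.02 and MX1 at -3.59. Inflammatory cytokine and NF-kB genes fell in 25 and rose in 3 of 30 cases (median -1.49, adjusted p = 2.32e-18), with CSF1 going from 1900 CPM to 331.4 and 333.9 CPM. In the IL6 receptor and JAK/STAT3 list 27 of 37 fell and 10 rose (median -0.76, adjusted p = 2.34e-09); the transcription factor gene CEBPD (-2.88) and the interleukin 4 receptor gene IL4R (-2.32) were among those that fell. Angiogenic factors and receptors fell in 37 and rose in 8 of 49 cases (median -1.07, adjusted p = 9.17e-07). CCN1 (-2.88) and PLAU, the urokinase gene (-1.70), fell, whereas HBEGF rose by 2.72; chosen after their values were seen, VEGFA fell by 0.90 ± 0.03 (442.6 CPM to 214.9 and 263.1 CPM) and VEGFC fell by 1.55. Matrix genes fell in 31 and rose in 6 of 39 cases (median -1.30, adjusted p = 1.52e-31), among them the collagen genes COL1A2 (587.4 CPM to 27.8 and 24.4 CPM) and COL3A1 (-6.23). Hypoxia and glycolysis genes fell in 22 and rose in 11 of 35 cases (median -0.47, adjusted p = 4.36e-06), with NDRG1, a gene induced by low oxygen, falling from 7553 CPM to 2048 and 2207 CPM. Without the span trend, the angiogenic median was -1.1 (adjusted p = 8.1e-09) and the matrix median shrank to -0.97 (adjusted p = 7.92e-30).

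GIST lineage genes in T1R rose in 5 and fell in 7 of 18 cases, with a median of 0.02, a mean of -0.32 and no call (adjusted p = 0.512). ETV1, a transcription factor of the GIST lineage, fell by 1.495 and PDGFRA, a receptor kinase gene mutated in some GIST, fell by 2.02, although a gene on the same strand overlaps PDGFRA and makes its count uncertain. MAPK output genes rose in 11 and fell in 12 of 26 cases (median -0.02, adjusted p = 0.732); ETV4 rose by 1.203 and EGR1 fell by 2.88. Bypass receptors, ligands and drug efflux genes fell in 22 and rose in 3 of 28 cases (median -1.003, adjusted p = 1.65e-05; median -0.63 and adjusted p = 0.0052 without the span trend), including HGF, the ligand gene of MET (-2.91). The BCL2 family list had 13 that fell and 12 that rose of 30 (median -0.09, adjusted p = 0.781), with BCL2L11 up by 2.995 and PMAIP1, which encodes NOXA, up by 1.34. Proliferation genes rose in 22 and fell in 17 of 40 cases (median 0.21, adjusted p = 0.00522, but adjusted p = 0.0691 with an estimated correlation, and a median of 0.03 with adjusted p = 0.239 without the span trend); E2F1 rose from 40.7 CPM to 296.3 and 258 CPM. p53 targets rose in 14 and fell in 10 of 28 cases (median 0.06, adjusted p = 0.441), with the DNA damage gene GADD45A up by 1.55. The ATF4 and unfolded protein list had 18 that fell and 11 that rose of 31 (median -0.30, adjusted p = 0.243; median -0.51 and adjusted p = 0.00308 without the span trend): the stress factor gene ATF3 rose by 2.86 and the chaperone gene HSPA5 fell by 1.18. Medians without the span trend were 0.07 for GIST lineage, -0.15 for MAPK output, -0.23 for BCL2 family and -0.09 for p53 target genes, again with no call.

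Cholesterol genes fell in 18 and rose in 5 of 23 cases in T1R (median -0.47, adjusted p = 1.9e-04), such as HMGCS1 (-1.42), an early enzyme of the pathway. Autophagy and lysosome genes rose in 25 and fell in 10 of 39 cases (median 0.20, adjusted p = 0.0387, but adjusted p = 0.0728 with an estimated correlation). The call ended without the span trend (median 0.16, adjusted p = 0.119). MAP1LC3B, a marker of autophagosomes, rose by 1.26. Interleukin and chemokine receptor genes fell in 17 and rose in 5 of 26 cases (median -0.90, adjusted p = 0.0456, but adjusted p = 0.0924 with an estimated correlation), and the decoy receptor gene IL13RA2 rose by 2.203. Ribosomal protein genes rose in 42 and fell in 1 of 44 cases (median 0.43, adjusted p = 6.55e-06, but adjusted p = 0.173 with an estimated correlation), for example RPL4 (0.76). Once the span trend was removed, 23 rose and 9 fell, without a call (median 0.12, adjusted p = 0.0789). Histones rose in 3 and fell in 5 of 11 cases, with a median of -0.15, a mean of 0.22 and no call (adjusted p = 0.976). Of these, 1 rose and 5 fell without the span trend (median -0.565, adjusted p = 0.498). Epithelial markers fell in 7 and rose in 3 of 11 cases (median -1.10, adjusted p = 0.0387, but adjusted p = 0.137 with an estimated correlation), endothelial markers fell in 6 and rose in 4 of 10 (median -1.53, adjusted p = 0.427), and blood cell markers rose in 7 of 8 (median 2.18, or 2.11 with HBA1 at its bound; adjusted p = 0.267). Of these, 8, 7 and 2 stood at 1 CPM or more in the control. Fibroblast and smooth muscle markers fell in 9 and rose in 2 of 15 cases (median -0.70, adjusted p = 2.34e-09), for example DCN (-2.47).

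The T1R counts were 11012 genes with sh1 (5398 higher, 5614 lower; 4108 at least 2-fold), 10884 with sh2 (5447 higher, 5437 lower; 3803 at least 2-fold) and 11292 with the mean of both (5589 higher, 5703 lower), or 80.2%. With both hairpins 4873 genes were higher and 5005 lower, against 2088 and 2167 for independent calls, and 78 went in opposite directions; the hairpins correlated at r = 0.957 across genes, against 0.52 in the simulations. Counts adjusted over the list alone equalled those over all genes in every list of T1R. The camera test called 14 of 22 lists, 9 with an estimated correlation, and fry called 22.

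**Figure D2:**
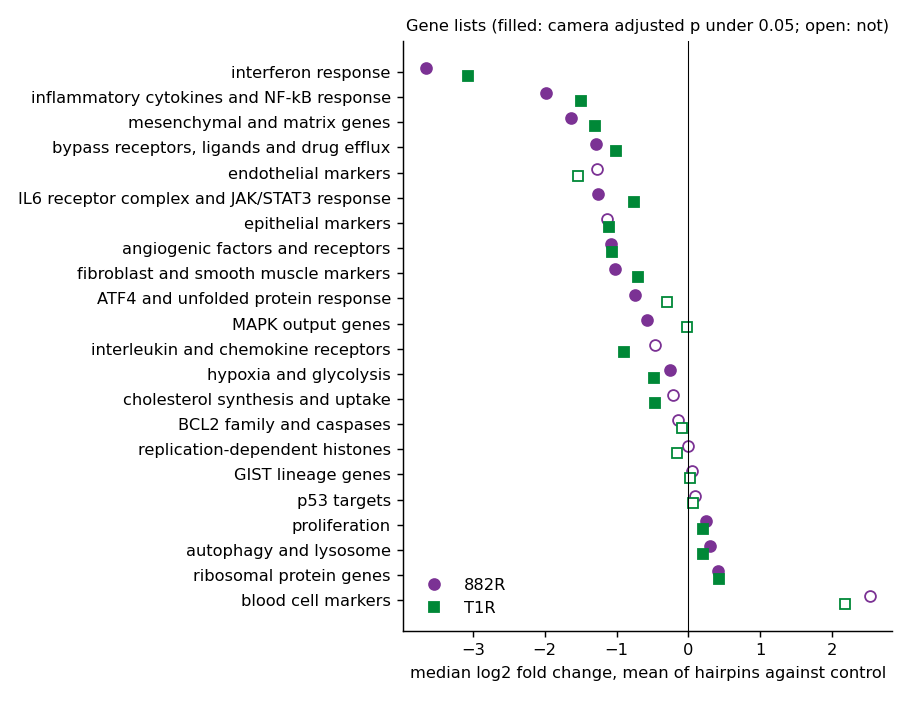
Median log2 fold change of the tested members of 22 gene lists, mean of both hairpins against control, in 882R (circles) and T1R (squares); filled symbols have a camera adjusted p under 0.05. The interferon response stands lowest at -3.66 and -3.07, and the blood cell markers, not called, highest at 2.53 and 2.18.

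Most genes called with both hairpins went the same way in both lines. Of these, 4028 were higher in both lines (1749 for independent calls, odds ratio 38) and 4258 were lower in both (1837, odds ratio 51.1; one-sided Fisher's exact tests), while 58 and 97 went in opposite directions. Genes lower in both lines by the most included the TGF-beta binding gene LTBP1 (-5.16 ± 0.16 in 882R and -5.36 ± 0.16 in T1R) and the kinase gene DCLK1 (-5.26 and -5.42). AOC3, a vascular amine oxidase gene, was among those higher in both (4.53 ± 0.14 and 4.77 ± 0.15), as was the neuronal transcription factor gene NHLH1 (4.30 and 3.93). Fold changes of the lines, which share no library, correlated at r = 0.885 (Spearman's rho 0.897, leave-one-out jackknife SE 0.0359) with a slope of 0.793 for T1R on 882R. All leave-one-out values (0.838 to 0.868) lay below 0.885, so this SE does not describe a spread centred on it. Averaged over both lines, 12274 genes were called (6159 higher, 6115 lower; 4451 at least 2-fold).

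**Figure D3:**
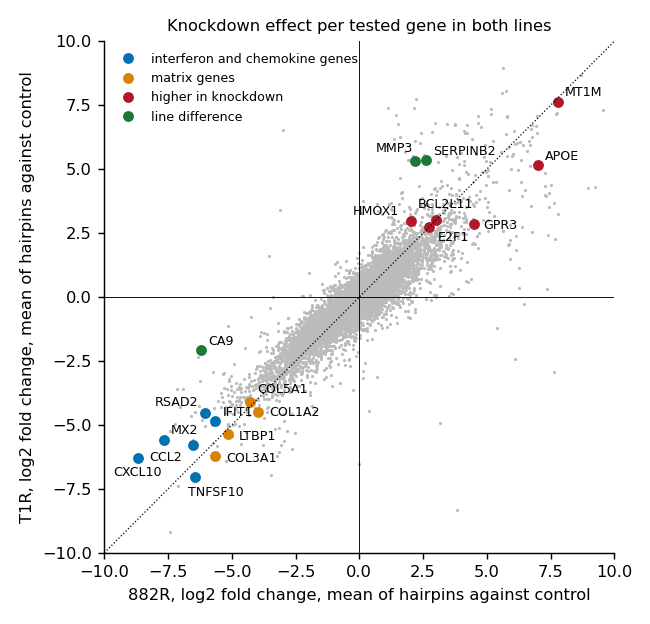
Knockdown effect (log2 fold change, mean of both hairpins against control) of each tested gene in 882R (horizontal) and T1R (vertical), with named genes coloured by group and the line of equality dotted; 4 of 14085 genes lie outside the axes. Genes gather along the diagonal (r = 0.885), and CA9 (-6.22 and -2.08) and MMP3 (2.19 and 5.34) stand off it.

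The lines also differed in the size of their response. CA9 fell by 6.22 in 882R but fell by 2.08 in T1R, a difference of 4.14 ± 0.11 on the log2 scale, and MMP3 rose by 2.19 in 882R and 5.34 in T1R, a difference of 3.14 ± 0.15. The cell cycle inhibitor gene CDKN2C rose by 1.34 in 882R and fell by 0.42 in T1R (difference -1.75 ± 0.08), and the chaperone gene HSPA2 rose by 3.98 and by 1.53 (difference -2.45 ± 0.20). IL6 fell less in T1R (difference 0.82 ± 0.09). By count, 6794 genes differed in effect (3804 with a more positive and 2990 with a more negative effect in T1R; 527 at least 2-fold). Of the lists, the interferon response fell less in T1R (30 members with a more positive effect, 4 with a more negative one, 3 not passed, median difference 0.62, adjusted p = 9.79e-15), and 19 of 26 MAPK output genes had a more positive effect, 0 a more negative one (median 0.38, adjusted p = 4.07e-07). Cholesterol genes had the more negative effect in T1R (median -0.26, adjusted p = 9.52e-08). The effect difference correlated at r = -0.775 across genes with the difference between the controls, which enter both quantities.

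The hairpins of a line differed less from each other than from the control. HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1, was higher with sh2 than with sh1 in both lines: 93.9 against 27.7 CPM in 882R (log2 difference 1.76 ± 0.05) and 137.1 against 56.7 CPM in T1R (1.27 ± 0.04). UVRAG, an autophagy gene (0.84 and 0.96), and the signalling gene DOCK9 (0.88 and 0.77) were also higher with sh2. The antiviral RNA sensors OAS1 (-1.91 ± 0.08 and -1.01 ± 0.06) and OAS2 (-1.44 and -0.98) and the keratin gene KRT5 (-1.31 and -1.32) were lower with sh2. In the interferon list, 30 of 37 genes were lower with sh2 in 882R and 3 higher (median -0.66), and 33 were lower in T1R and 0 higher (median -0.45). By count, 6334 genes differed between hairpins in 882R (2881 higher with sh2, 3453 lower; 352 at least 2-fold) and 4439 in T1R (2307 higher, 2132 lower; 55 at least 2-fold; 2752 by DESeq2). In both lines 790 were higher with sh2 (471.9 for independent calls) and 1121 lower (522.7), while 256 and 477 went in opposite directions; across genes the hairpin differences of the lines correlated weakly, at r = 0.173 (Spearman's rho 0.238, SE 0.0857). It was r = 0.0996, 0.0896 and 0.1008 without 882R sh1 replicate 2, 882R sh2 replicate 2 and T1R sh2 replicate 1. MX2, an antiviral gene lower with sh2 (-1.76 in 882R, -1.41 in T1R), lost its call without sh2 replicate 2 of the line (-1.44, adjusted p = 0.0565, and -0.94, adjusted p = 0.0609).

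The controls of the lines were compared to learn how they differ from each other. SERPINB2, a plasminogen activator inhibitor gene whose count is uncertain because SERPINB10 overlaps it, was lower in the T1R control (log2 fold change -3.06 ± 0.19), as were MMP3 (-1.997 ± 0.15) and the growth arrest gene GADD45A (-1.87 ± 0.04). Higher in the T1R control were HSPA2 (1.77 ± 0.19), the GDNF family receptor gene GFRA2 (1.84 ± 0.19) and CCNG2, a cyclin gene of growth arrest (1.38 ± 0.09). Interferon response genes were lower in 26 and higher in 4 of 37 cases (median -0.31, adjusted p = 1.73e-15), p53 targets lower in 15 and higher in 5 of 28 (median -0.22, adjusted p = 1.13e-10), cholesterol genes higher in 19 and lower in 0 of 23 (median 0.30, adjusted p = 4.03e-23) and proliferation genes higher in 25 and lower in 7 of 40 (median 0.19, adjusted p = 1.47e-06). GIST lineage genes were higher in 7 and lower in 1 of 18 cases (median 0.12, adjusted p = 0.0173, but adjusted p = 0.0592 with an estimated correlation). Altogether 5998 genes differed (2864 higher in T1R, 3134 lower), 304 of them at least 2-fold, and control libraries of different lines correlated at r = 0.986 to 0.987, close to the 0.992 to 0.993 of replicates. DESeq2, run separately, called 3951 genes in this comparison.

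The knockdown effect followed the genomic span of genes, a comparison chosen after seeing the data. In 882R, the median log2 fold change went from 0.53 over 1141 genes under 5 kb to -1.91 over 432 genes above 200 kb, and in T1R from 0.29 to -1.34. Long genes named above, such as EGFR (-2.87 in 882R), MET and ATG7, lay at the low end. Spearman's rho between span and effect was -0.541 in 882R and -0.400 in T1R over 10779 genes, and -0.0182 for the difference between the controls. With the trend removed, IL6 kept log2 fold changes of -3.68 and -5.31 in 882R and -3.07 and -3.77 in T1R, and the interferon list kept medians of -3.61 and -3.28. Of the named effects of at least 0.5 in size, 35 of 153 in 882R and 18 of 151 in T1R moved by over 1.5 times. Of the effects given above for 882R, those of EGFR (-1.745 without the span trend), MET (-1.635), ABCC1 (-1.312), ATG7 (-0.827), ERG (-1.212), BARX1 (0.344), RPL15 (0.134) and CDKN2C (0.775) shrank by as much, and those of KRT18 (-1.724) and RPL3 (-1.187) grew. In T1R, that of RPL4 shrank to 0.485.

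**Figure D4:**
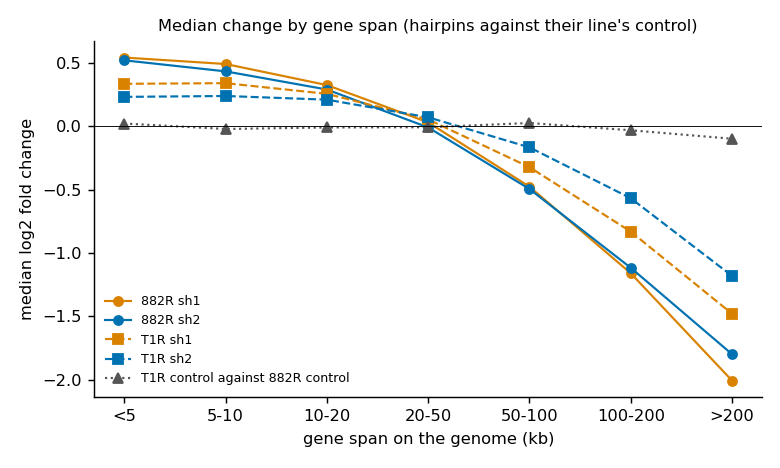
Median log2 fold change of genes grouped by genomic span (kb), for each hairpin against the control of its line (882R solid, T1R dashed) and for the T1R control against the 882R control (dotted). With knockdown the medians pass from above 0 under 20 kb to below -1 above 200 kb, while the control comparison stays between -0.1 and 0.02.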

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

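The counts over other splits of the libraries were planned before the data were examined, and the look at which splits exceeded the real one was chosen only after the result was seen. The results here stood out because the knockdown effect differed between the lines by a test of the difference itself, T1R minus 882R on the log2 scale. Unequal controls enter this difference, which correlated at r = -0.775 across genes with the T1R control against the 882R control. For IL6, the controls held 221.4 CPM in 882R and 111 CPM in T1R. The knockdown groups held 26.4 and 17.4 CPM with sh1 and 8.22 and 9.69 CPM with sh2. Differences in effect are therefore not all differences in the state after knockdown.

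IL6 fell less in T1R than in 882R (0.82). The largest positive differences were those of the hypoxia gene CA9 (4.14), the protease gene MMP3 (3.14), the protease inhibitor gene SERPINB2 (2.72, overlapped by SERPINB10), the chemokine gene CXCL10 (2.39) and FRMD5, a gene of cell adhesion (2.37), which fell by 5.36 in 882R and fell by 2.99 in T1R (-1.729 without the gene span trend). The largest negative differences were those of HSPA2 (-2.45), APOE (-1.85), CDKN2C (-1.75), the receptor gene GPR3 (-1.65; it rose by 4.51 in 882R and 2.87 in T1R) and the adaptor gene DOK4 (-1.55; log2 fold change 1.41 in 882R, or 0.905 without the span trend, and -0.14 in T1R, not called but called as a fall without the span trend). The CXCL10 difference was 4.41 without 882R sh2 replicate 1. The APOE difference lost its call when any 1 of the 4 control libraries was left out: -1.60 (adjusted p = 0.116) without 882R control replicate 1, -2.15 (adjusted p = 0.05) without replicate 2, -1.84 (adjusted p = 0.074) without T1R control replicate 1 and -1.86 (adjusted p = 0.0948) without replicate 2.

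Among the gene lists, the median difference was positive for the interferon response (0.62, adjusted p = 9.79e-15), MAPK output genes (0.38, adjusted p = 4.07e-07), ATF4 and unfolded protein response (0.21, adjusted p = 4.31e-06), bypass receptors, ligands and drug efflux (0.20, adjusted p = 9.04e-05, but 0.04 with adjusted p = 0.0185 once the gene span trend was removed), and p53 targets (0.13, adjusted p = 9.15e-04). It was positive too for inflammatory cytokines and NF-kB response (0.20, adjusted p = 4.89e-05, but adjusted p = 0.0626 with an estimated correlation) and for the IL6 receptor complex and JAK/STAT3 response (0.093, adjusted p = 0.00502, but adjusted p = 0.0993 with an estimated correlation). The difference was negative for cholesterol synthesis and uptake (-0.26, adjusted p = 9.52e-08), for proliferation (-0.16, adjusted p = 1.41e-04, but adjusted p = 0.0558 with an estimated correlation, and -0.04 without the span trend) and for fibroblast and smooth muscle markers (-0.28, adjusted p = 0.0242, but adjusted p = 0.0863 with an estimated correlation). Differences grew without the span trend for the inflammatory list (0.505, adjusted p = 2.34e-10), the IL6 receptor list (0.257, adjusted p = 3.54e-07), the ATF4 list (0.364, adjusted p = 2.56e-16) and p53 targets (0.242, adjusted p = 3.08e-09).

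In all, 6794 genes differed in their effect between the lines. When the 2 controls of each line were drawn in 100 of the 225 possible ways, 7 splits, the real one included, gave as many genes, and the highest of the others gave 11773. The 6 others kept the real controls in 1 line and took 2 knockdown libraries as the controls of the other. The knockdown effect itself is then part of the line difference, so their counts (10395 to 11773) follow from the structure of the samples and do not decide about chance. The 8 splits with the real controls in 1 line and 1 control and 1 knockdown library as controls of the other gave at most 171 genes, and splits with the real controls in neither line at most 5334. A group that mixes control and knockdown libraries has a wide spread, so the low counts of the 8 splits also follow from the structure. None of these counts decides about chance.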

How the results depend on the processing

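Removal of the gene span trend was chosen after seeing the data; all other alternatives were planned. Under RLE scaling, 382 of the values of named genes kept their direction and call. The stricter filter kept 379 and weakened 1, no filter kept 381 and weakened 1, DESeq2 kept 376 and weakened 4, and fits of a line alone kept 348. With replicate number as a block, 380 were kept and 2 weakened, and IL6 in 882R with sh1 stayed at -3.07; the replicate numbers show no pairing, since deviations from group means correlated at r = -0.0589 to 0.0493 across groups. Leaving out 1 library kept 4557 values and weakened 27.

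Requiring a log2 fold change of at least 1 lowered the counts by construction: to 4719 (sh1), 5221 (sh2), 4972 (mean) and 4128 (both hairpins) in 882R, to 4108, 3803, 3983 and 3351 in T1R, to 4451 over both lines, 527 for the line difference, 352 and 55 for sh2 against sh1 in 882R and T1R, and 304 for the controls. DESeq2 called 2752 genes for sh2 against sh1 in T1R and 3951 for the controls; the cause was not tested. The correlation between lines was 0.838 to 0.868 with 1 library left out, against 0.885, and the overlap of lines was 7932 to 8175 genes. With an estimated correlation, the lists called fell to 9 in T1R and 6 for the line difference; fry, which does not compare a list with other genes, called 22 in each line, 17 for the line difference and 18 for the controls.

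Without the span trend, 366 values of named genes were kept, 4 gained a call, 4 weakened and 4 turned: CD68 (-0.068), RPL6 (-0.106) and RPS12 (-0.14) in 882R and UVRAG in T1R (0.27). Of the lists, ribosomal protein genes in 882R turned (median 0.41 to -0.18) and lost their call (adjusted p = 0.298). Calls also ended, with smaller medians, for ribosomal protein genes (0.0789) and proliferation (0.239) in T1R and for autophagy in 882R (0.126) and T1R (0.119). Calls were gained in 882R for p53 targets (0.0119), cholesterol (0.00441) and epithelial markers (0.00174), in T1R for the ATF4 list (0.00308), and in the line difference for GIST lineage (0.0361), BCL2 family (0.0497), hypoxia (0.00284) and ribosomal protein genes (1.09e-13). The trend moves with the knockdown, so whether these are its effect was not tested.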

Other observations

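Apart from the other splits of the libraries, all tests of explanations in this part were chosen only after the result was seen, and the genes of the next paragraphs were named after their values were seen.

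Of 8 tested metallothionein genes, which bind zinc and copper, 8 were higher with IL6 knockdown in 882R and 7 in T1R, against 41.8% and 39.7% of all tested genes. Genes under 5 kb rose as a class (medians 0.53 and 0.29), so the share over all genes is a low background for short genes. Without the span trend, 8 and 7 of the family were still called higher. Near-identical copies can share reads, so these are not independent rises, and the family was not tested as a list. MT2A was up by 1.55 (0.976 without the gene span trend) and 1.93 and MT1X by 0.90 (0.315 without it) and 0.92 on the log2 scale. The hairpins differed for MT1X: it rose by 0.317 with sh1 and 1.489 with sh2 in 882R, and by 0.765 and 1.08 in T1R. Near-identical copies make the single counts uncertain. Among single genes outside this family, the ferritin light chain gene FTL, for iron storage, rose by 2.50 and 2.51 and the heavy chain gene FTH1 by 0.94 (0.333 without the span trend) and 1.06. HMOX1, which releases iron from haem, rose by 2.01 ± 0.06 and 2.98 ± 0.06. These means join 1.135 with sh1 and 2.894 with sh2 in 882R, and 2.348 and 3.621 in T1R, a difference that the SE leaves out.

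Other single genes changed in both lines. POLR2A, the largest subunit of RNA polymerase II, went from 108.7 CPM to 648.3 and 780.1 CPM in 882R and from 94.5 CPM to 881.1 and 849.3 CPM in T1R. HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose by 3.09 ± 0.04 and 1.88 ± 0.04, and the chromatin reader gene BRD2 by 1.47 and 1.61. The proto-oncogene MYC fell by 0.84 in 882R and had a log2 fold change of 0.18 in T1R (-1.423 and -0.152 without the span trend). The receptor gene IL6ST had log2 fold changes of -1.27 and -0.76 and the receptor gene OSMR of -2.33 and -1.46.

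Across all 8 knockdown libraries, long genes were lower and short genes higher than in the controls, with standardised span coefficients of -0.569 in 882R and -0.390 in T1R. At equal span, for the mean of both hairpins, transcript length had a coefficient of -0.0105 in 882R and 0.0021 in T1R and GC content of -0.0038 and -0.0644. Single hairpins reached -0.0234 for length with sh2 in 882R and -0.0868 for GC content with sh2 in T1R. With span left free, Spearman's rho with the effect was -0.323 and -0.223 for length and 0.2 and 0.0884 for GC content. The values at equal span argue against loss of long or fragmented RNA and against GC bias as the main source of the trend. Length and GC content were those of the longest annotated transcript, so this holds as far as it stands for the expressed one. If the extent of IL6 depletion set the trend, sh2 should have the steeper one, yet its span coefficient against sh1 was positive in 882R (0.0596 ± 0.0039, SE) and in T1R (0.0911 ± 0.0023). This SE is over genes and leaves out the spread between libraries. The 2 controls of a line differed in span slope by 0.0111 in 882R and 0.0206 in T1R. The hairpins also differ in sequence, and between the lines the larger fall of IL6, in 882R, went with the steeper trend. These values do not decide whether the extent of depletion matters. A batch shared by the control libraries cannot be told apart from the knockdown, because the labels give no batch and the hairpins of a line differ by at most 0.0911. An effect of the knockdown or of the hairpin vectors on transcription of long genes may also underlie it and was not tested.

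Interferon response genes fell in every knockdown group, and IFNB1, the interferon beta gene, fell by 3.34 in 882R and fell by 2.76 in T1R from 2.61 and 0.888 CPM. The gene span trend does not account for it, as the list median without that trend was -3.28 or lower in both lines. The level may follow IL6: sh2, which left less IL6, had the lower interferon list in both lines (median difference -0.45 or lower, with 30 of 37 genes lower in 882R and 33 in T1R), though the hairpins also differ in sequence. A condition of the control libraries unrelated to IL6, such as a response to what the control cells carry, cannot be told apart from the knockdown, because the difference between hairpins (at most -0.66 in size) is small beside that from the controls. No sample with IL6 lowered and then restored is among the groups.

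The control libraries of the lines were nearly alike. Between them, 0 genes stood at 10 CPM or more in one and under 0.5 CPM in the other, against 13 to 22 between a control and its own knockdown groups, and of 9719 genes above a log2 CPM of 3, 2 were over 4-fold apart and 72 over 2-fold. Such values would arise if both line labels held cells of one origin, a hypothesis that expression alone does not settle. The column names of the T1R libraries, which begin with T882, bear on it too but do not settle it either. An exchange of a single library between the lines is argued against, since 12 of 12 libraries correlated best with the other library of their own group. An exchange of both libraries of 1 hairpin would leave that count as it is, but the T1R minus 882R differences of sh1 and sh2 correlated positively across genes (r = 0.341 at the lowest between single libraries), which argues against it. An exchange of both control libraries cannot be told apart from the labels as given, because the line difference of the controls correlated only weakly with those of the hairpins (r = 0.0607 to 0.113 with sh1 and 0.0189 to 0.127 with sh2), although all of these values are positive where an exchange would make them negative. The GIST marker gene ANO1, chosen after its values were seen, was at 0.31 CPM in the 882R control and 0.66 CPM in the T1R control. That is 8 and 5 reads in the 882R control libraries and 10 and 16 in those of T1R. Of the 18 tested GIST lineage genes, 15 stood at 1 CPM or more in the 882R control and 14 in the T1R control. The GIST identity of the cells is taken from the labels and was not tested.

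For the effect averaged over both lines, 1 of 100 splits, the real one, called 12274 genes or more, and the highest of the others called 11054. A group that mixes control and knockdown libraries has a wide spread, so such splits call few genes by construction. The split with 11054 genes took both libraries of a hairpin as the controls of each line, so it still holds the knockdown effect. The ranking of the real split therefore does not decide about chance.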
